A study of Homo sapiens with 21 samples.

How the data were processed

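Gene expression was measured in whole peripheral blood of heart transplant recipients on Affymetrix oligonucleotide arrays, with 1 array per sample and 21 arrays in all. Blood RNA was stabilised in PAXgene tubes, extracted with Trizol and labelled as biotinylated cRNA, per the labels' protocols. The deposited values are log2 probe set summaries that the authors made with RMA (background correction, quantile normalization and summary over the probes of a set), per the submitters' processing notes. The version of RMA and the set of arrays normalized together are not given in the sources used here. The log2 scale was read from the values, which ran from 2.46 to 14.4. RMA values carry no count behind them, so the number of arrays limits the precision.

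The table held 22283 probe sets, of which 19071 had 1 gene symbol in the platform annotation, 1043 had several and 2169 had none in the table used. No gene was named from a probe set with several symbols. The annotation was set against RefSeq names of assembly GRCh38.p14 by gene identifier. It updated 0 symbols. XIST and Y-linked genes, 52 probe sets in all, were left out before any step, and 68 array control probe sets entered no gene test. Each of the 11939 genes was represented by its probe set with the highest mean over all 21 arrays. The 8255 genes with that mean above the 40th percentile of all probe sets (log2 5.31) were tested. Since 4304 genes had more than 1 probe set, the 11634 probe sets with 1 gene symbol above that level were also tested singly as an alternative. Probe sets below that level did not enter this alternative.

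The labels placed 7 samples in each of the groups rejection, follow-up and control. The labels also state that each follow-up sample is paired with the rejection sample of the same number, so follow-up against rejection was fitted with the patient as a block. The consensus correlation of the paired samples was 0.296 over all genes. The controls have no stated partner, and the comparisons with them had no block. Array medians ranged from 5.66 to 5.82, pairwise correlations of arrays ranged from 0.933 to 0.992, and 0 columns were identical.

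Each comparison was fitted in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend) on the 14 samples compared. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Before the data were examined, 25 gene lists were fixed for blood cell types, interferon and T cell responses, drug responses, blood handling and basic cell machinery. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 25 lists. Differences of list means between groups were tested by exact permutation, two-sided, within patients for the paired comparison. The return of rejection genes after treatment was measured on genes chosen with 3 of the 7 rejection samples and followed in the other 4 patients, over all 35 such divisions. Its null came from swapping rejection and follow-up within patients, with 100 draws including the real one, one-sided.

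Named genes followed a rule fixed before the data were examined. In each comparison, up to 10 genes per direction with the largest differences among those past the threshold were to be named, and where fewer than 5 passed, the genes of smallest p filled the direction up to 5 and are said not to pass. In the paired comparison a passing gene also had to change the same way in at least 6 of 7 pairs. Up to 4 members of smallest p of each list, and every kept member of a panel of genes used in a blood test for cardiac rejection, could also be named. HLA, KIR, immunoglobulin and T cell receptor segment genes and a few genes whose level follows inherited variants were not named.

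The alternatives were quantile normalization, median centring, 2 other filters, other probe set rules, robust and untrended eBayes, array quality weights, a fit of all 21 samples with the patient as a random block, a block on the replicate number or its removal, and a threshold of 0.10. Fits with marker list means or with the 3' minus 5' values of GAPDH and ACTB as covariates, and fits leaving out each sample or pair in turn, were added after seeing the data. The gene test was tested on simulated data with 200 changed genes among 8255 and noise independent between genes. For rejection against control it recovered 52% of genes changed by 0.5 on the log2 scale, 88% of those changed by 1, 98% at 1.5 and 96% at 2, with 6 false calls among 173. For follow-up against rejection the recovered shares were 74%, 94%, 100% and 100%, with 10 false calls among 194. For follow-up against control they were 70%, 94%, 96% and 100%, with 11 false calls among 191. Each size was given to 50 genes, and the large changes ease the adjusted threshold for the small ones. In the real comparisons 3, 0 and 5 genes differed by over 2-fold, and genes were correlated. The recovered shares therefore do not show which changes would be found in these data.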

Results

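The study took whole blood from heart transplant recipients in 3 groups of 7 samples each. The first group had acute cellular rejection, in which recipient lymphocytes infiltrate the graft. The second held follow-up samples of the same patients after treatment of the rejection, and the third held control recipients with no rejection. Whole blood mixes neutrophils, lymphocytes, monocytes, platelets and young red cells, so a value reflects both the share of each cell type and its expression. The comparisons ask how blood expression differed during rejection and whether it moved after treatment. Values are log2 RMA signals, given as mean ± SD (n = 7) for groups and with the standard error (SE) for differences.

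On average, blood taken during rejection had higher signals of ribosomal protein and T cell genes and lower signals of neutrophil genes than control blood. No single gene passed the test, and these differences of list means did not pass when tested between samples. Of 41 cytosolic ribosomal protein genes, 40 were higher, with a median difference of 0.41. Of 14 T cell markers 13 were higher, with a median of 0.34, and all 15 neutrophil markers were lower, with a median of -0.40. In limma's camera with a preset correlation these lists had adjusted p of 3.78e-13, 5.63e-06 and 9.64e-05. The estimated correlation between genes was 0.86, 0.69 and 0.71, and with it each of the 3 had an adjusted p of 0.756. The 3 list means also followed one another with group means removed. Pearson r was 0.83 for T cell with ribosomal, -0.72 for T cell with neutrophil and -0.61 for ribosomal with neutrophil. They are therefore not 3 separate findings. The spread between patients was wide: the ribosomal list mean was 9.90 ± 0.48 in rejection and 9.42 ± 0.81 in controls (exact permutation p = 0.200, two-sided), the T cell mean 7.59 ± 0.59 and 7.19 ± 0.39 (exact p = 0.154), and the neutrophil mean 9.07 ± 0.60 and 9.44 ± 0.43 (exact p = 0.202). Each has an adjusted exact p of 0.824 over the 25 lists. Leaving out 1 sample at a time, the ribosomal difference of list means went from 0.48 to as little as 0.28, that of T cell markers from 0.40 to 0.29 and that of neutrophil markers from -0.38 to -0.24.

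Among ribosomal genes, RPS25 was higher by 0.90 (SE 0.32), RPL22 by 0.97 (SE 0.42) and RPL11 by 0.77 (SE 0.32). Among T cell markers, LEF1, a transcription factor of naive T cells, was higher by 1.06 (SE 0.39), CD3D, a chain of the T cell receptor complex, by 0.78 (SE 0.42), and CCR7, a lymph node homing receptor, by 0.64 (SE 0.34). CSF3R, the receptor for granulocyte colony-stimulating factor, was lower by -0.77 (SE 0.24), and FPR1, a receptor for bacterial formyl peptides, by -0.57 (SE 0.23). Other probe sets above the filter gave 0.35 to 0.93 for RPL22 and -1.12 for FPR1. None of these genes passed over all genes (adjusted p from 0.967 to 0.977 in limma), and 0 members of any of the 3 lists passed adjusted over the list alone.

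Erythroid genes were also higher in rejection, 16 of 19 with a median of 0.28, including the haem synthesis genes FECH at 0.59 (SE 0.33, another probe set 0.26) and ALAS2 at 0.64 (SE 0.46). Cytotoxic lymphocyte genes were higher in 15 of 17, with a median of 0.24, and CD8A differed by 0.47 (SE 0.28). Respiratory chain genes (27 of 36 higher, median 0.10) and proteasome genes (20 of 28 higher, median 0.10) were higher. Of the respiratory chain genes 1, UQCRB, passed adjusted over its list alone (adjusted p = 0.0142). Immediate early genes (11 of 15 lower, median -0.14) and glucocorticoid induced genes (13 of 17 lower, median -0.12) were lower, with IER3 at -0.40 (SE 0.15) and CEBPD at -0.68 (SE 0.38). With group means removed, the means of both lists followed that of the neutrophil markers over the 21 samples (Pearson r = 0.895 and 0.867, Spearman rho = 0.899 and 0.897, r = 0.859 and 0.835 without the 2 samples farthest from the median). The permutation p was 1e-05 each, the smallest the permutations can give, and 1.5e-05 adjusted over 3 relations. The permutations took the samples as independent, though rejection and follow-up samples share patients. These 6 lists had camera adjusted p of 0.0109, 0.0316, 0.0167, 0.0265, 0.0265 and 0.0375 in that order. With an estimated correlation the adjusted p was 0.756 for immediate early genes and 0.881 for the other 5. All 6 preset calls depended on single samples: leaving out each of the 14 samples in turn ended the calls in 5, 7, 6, 6, 5 and 8 of the 14, in the same order. The differences of list means, in that order, went from 0.27 to as little as 0.15, from 0.21 to 0.02, from 0.14 to 0.05, from 0.12 to 0.03, from -0.17 to -0.11 and from -0.23 to -0.13.

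**Figure D1:**
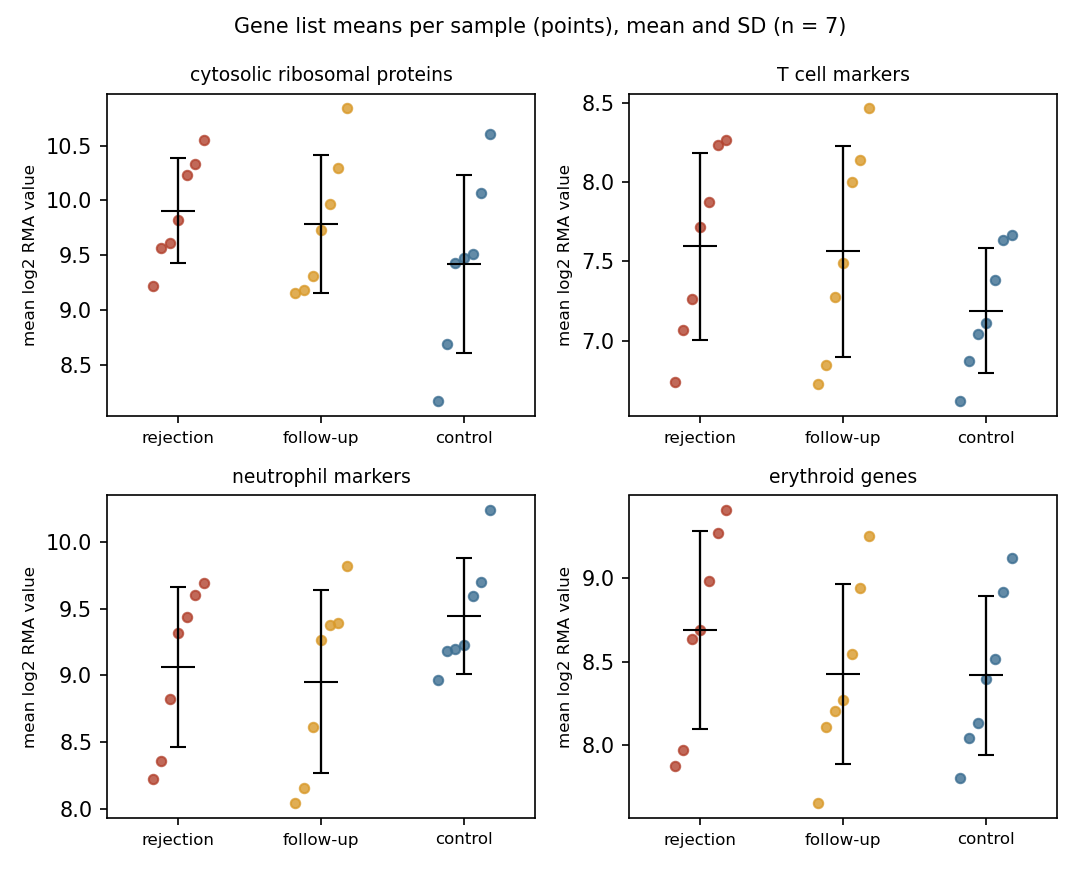
Mean log2 RMA value of 4 gene lists (vertical axes) in the 7 samples of each group (horizontal axes), with points for samples and bars for the group mean and SD. The ribosomal mean was 9.90 in rejection, 9.78 at follow-up and 9.42 in controls, with overlapping samples.

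The remaining 16 lists did not pass. Type I interferon genes were higher in 18 of 22 with a median of 0.19 (camera adjusted p = 0.0724), and IFI27, an interferon induced gene, was at 7.58 ± 1.17 in rejection and 6.65 ± 0.32 in controls. Interferon gamma induced genes had a median of -0.04 (adjusted p = 0.702), with CXCL9, a chemokine that draws T cells, at -0.14 (SE 0.09). T cell activation genes had a median of -0.03 and a mean of 0.02 (adjusted p = 0.749). Proliferation genes had a median of -0.03 (adjusted p = 0.702), with MKI67 at -0.23 (SE 0.07, another probe set -0.02) and MCM6 at 0.26 (SE 0.09). Monocyte markers had a median of -0.17 (adjusted p = 0.223). The 8 kept members of the blood rejection test panel were divided evenly between directions (adjusted p = 0.842): ITGA4, an integrin chain of lymphocytes and monocytes, was at 0.65 (SE 0.43), the decoy interleukin receptor IL1R2 at -0.95 (SE 0.67), ITGAM at -0.29 (SE 0.26, another probe set -0.07), MPIG6B at 0.13 (SE 0.10), MARCHF8 at 0.19 (SE 0.24), FLT3 at -0.10 (SE 0.11), SEMA7A at -0.06 (SE 0.13) and the platelet gene PF4 at 0.05 (SE 0.35).

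In limma, 0 of 8255 genes differed between rejection and control at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 368, where 413 are expected of independent genes. Other splits of the samples gave a median of 240, and 41 of 100 splits reached 368. The lowest adjusted p was 0.650. The genes of smallest p, which did not pass, were higher for UQCRB, a subunit of respiratory complex III (7.18 ± 0.54 against 6.02 ± 0.55, a difference of 1.17, SE 0.26), BTF3 (0.66, SE 0.14), CUL4A, a ubiquitin ligase scaffold (0.42, SE 0.09), TERF2IP (0.39, SE 0.09) and GMPS, an enzyme of guanine nucleotide synthesis (0.29, SE 0.06). They were lower for SCD5 (-1.01, SE 0.26), CFLAR, an inhibitor of death receptor signalling (-0.84, SE 0.21), PIGB (-0.46, SE 0.09), UBQLN4 (-0.35, SE 0.08) and GDPD3 (-0.24, SE 0.06). Other UQCRB probe sets gave 0.75 and 0.05, so the probe sets of this gene differed, and those of CFLAR ranged from -0.42 to -0.88. Array quality weights gave 999 genes at an unadjusted p under 0.05 and still 0 past the threshold, though the lowest adjusted p in limma fell to 0.070.

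After treatment, signals of immature granulocyte and erythroid genes were on average lower than in the same patients during rejection. Neither list mean passed when tested over the pairs. All 12 immature granulocyte genes, which encode granule proteins made in the bone marrow, were lower, with a median change of -0.34 (camera adjusted p = 1.22e-08), and 18 of 19 erythroid genes were lower, with a median of -0.29 (adjusted p = 4.88e-06). With an estimated correlation both had an adjusted p of 0.921. ELANE, neutrophil elastase, changed by -0.33 (SE 0.17), LTF, lactoferrin, by -0.46 (SE 0.26), AHSP, a haemoglobin chaperone, by -0.49 (SE 0.29) and EPB42 by -0.45 (SE 0.27), and none of them passed (adjusted p = 0.9995 in limma). The list means moved from 6.72 ± 0.83 to 6.41 ± 0.42 (exact p = 0.188, lower in 5 of 7 pairs) and from 8.69 ± 0.59 to 8.43 ± 0.54 (exact p = 0.375, lower in 5 of 7 pairs). Adjusted over the 25 lists, both exact permutation p were 0.934. Without the pair of the largest change, the medians were -0.11 and -0.10, and 0 and 1 of the 7 omissions of a pair ended the preset calls.

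**Figure D2:**
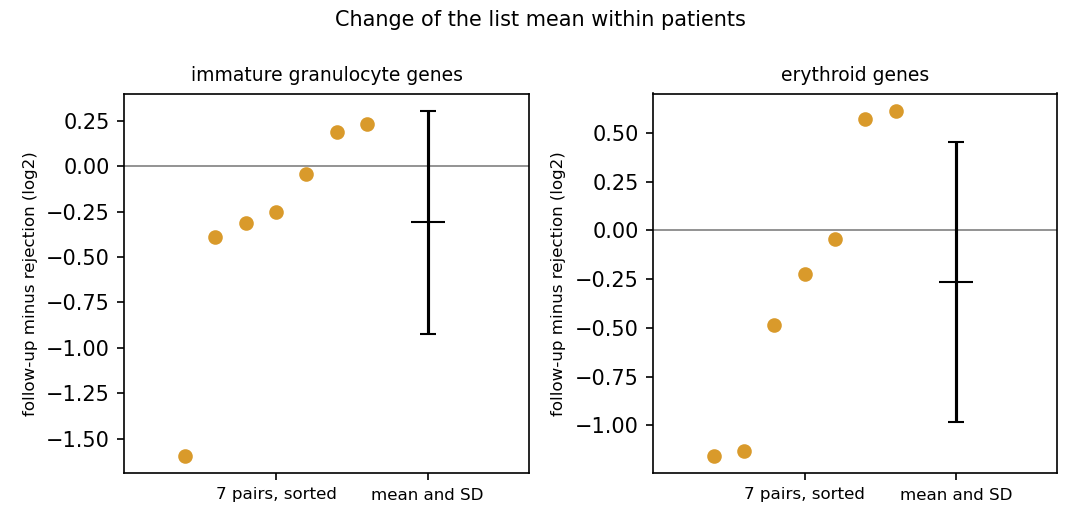
Follow-up minus rejection change of the mean of the immature granulocyte list (left) and the erythroid list (right) on the log2 scale (vertical axes), with a point for each of the 7 pairs in sorted order and the mean and SD beside them. In both lists 5 of 7 pairs lie below 0, and the lowest are at -1.59 and -1.16.

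Ribosomal genes (34 of 41 lower, median -0.07, adjusted p = 0.00129) and neutrophil markers (13 of 15 lower, median -0.10, adjusted p = 0.0271) were slightly lower at follow-up. The changes of these list means were -0.12 and -0.11, and each became 0.03 with 1 of the pairs left out. Leaving out each of the 7 pairs in turn ended the ribosomal call in 2 and the neutrophil call in 3. Interferon gamma induced genes (15 of 16 higher, median 0.08, adjusted p = 0.0387) and cytotoxic genes (12 of 17 higher, median 0.10, adjusted p = 0.0438) were slightly higher, with CXCL9 at 0.15 (SE 0.08), the peptide transporter TAP2 at 0.14 (SE 0.08), GNLY, granulysin, at 0.47 (SE 0.23) and GZMM at 0.25 (SE 0.11). With 1 pair left out the changes of these list means went from 0.09 and 0.10 to as little as 0.05 each, and 4 and 3 of the 7 omissions ended the calls. With an estimated correlation each of these 4 had an adjusted p of 0.921, and without the patient block 3 lists passed the preset test in place of 6. The T cell list had a median of 0.02 (adjusted p = 0.786), the T cell activation list a median of 0.01 (adjusted p = 0.708), and the glucocorticoid list a median of -0.10 (adjusted p = 0.0732), with TSC22D3, a steroid induced leucine zipper gene, at -0.26 (SE 0.24). In limma 0 genes passed, 186 had an unadjusted p under 0.05 (reached by 33 of 64 swaps within patients), and the lowest adjusted p was 0.9995. The genes of smallest p, which did not pass, were higher for STAG3L3 (0.43, SE 0.09), USP34 (0.41, SE 0.10), TSR1 (0.30, SE 0.08), UBQLN4 (0.29, SE 0.07) and KLHL28 (0.26, SE 0.07). They were lower for UQCRB (-0.79, SE 0.21), OPTN, an autophagy receptor (-0.45, SE 0.12), SLC66A2 (-0.37, SE 0.08), RAB5C, an endosome GTPase (-0.33, SE 0.09) and CETN2 (-0.24, SE 0.06). The USP34, TSR1 and UBQLN4 probe sets are of the kind Affymetrix marks as able to bind other transcripts, and another USP34 probe set changed by -0.03 (SE 0.10). Other probe sets gave -0.54 and -0.05 for UQCRB, -0.16 for OPTN and -0.09 for TSC22D3.

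On average, follow-up blood still had lower neutrophil and higher T cell and cytotoxic signals than control blood. These differences of list means did not pass when tested between samples. All 15 neutrophil markers were lower with a median of -0.50 (camera adjusted p = 9.02e-09), all 12 immature granulocyte genes were lower with a median of -0.42 (2.11e-07), all 41 ribosomal genes were higher with a median of 0.36 (1.94e-07), all 14 T cell markers were higher with a median of 0.34 (8.49e-06) and 16 of 17 cytotoxic genes were higher with a median of 0.32 (6.15e-05). With an estimated correlation the adjusted p was 0.434, 0.434, 0.728, 0.533 and 0.554. For the list means, the exact permutation p, two-sided, was 0.138, 0.123, 0.372, 0.222 and 0.287 in the same order. Adjusted over all lists, these exact p were 0.595, 0.595, 0.907, 0.694 and 0.796. FPR1 differed by -0.66 (SE 0.26), the defensin DEFA4 by -1.08 (SE 0.44), LEF1 by 0.85 (SE 0.46) and GNLY by 0.71 (SE 0.47). B cell markers, higher in 7 of 10 with a median of 0.05, did not pass (adjusted p = 0.511). Leaving out 1 sample at a time, the differences of list means went from -0.49 to as little as -0.34 for neutrophil markers, from -0.54 to -0.37 for immature granulocyte genes, from 0.36 to 0.15 for ribosomal genes, from 0.37 to 0.22 for T cell markers and from 0.32 to 0.15 for cytotoxic genes, and 0 of 14 omissions ended any of these 5 preset calls.

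Of the other lists past the preset test, type I interferon genes were higher in 20 of 22 (median 0.27, adjusted p = 0.0123, 0.832 with an estimated correlation), with IFI27 at 1.04 (SE 0.61). The interferon difference of list means was 0.28, and -0.01 without 1 of the follow-up samples (camera adjusted p = 0.972), and 5 of 14 omissions ended the call. Glucocorticoid induced genes (15 of 17 lower, median -0.15, adjusted p = 0.000105), immediate early genes (11 of 15 lower, median -0.16, 0.00209), dendritic cell markers (9 of 10 lower, median -0.05, 0.0190) and NF-kB genes (8 of 11 lower, median -0.07, 0.0429) were lower. With an estimated correlation the adjusted p was 0.524 for the first and 0.434 for the other 3. Of the 14 omissions of a sample, 0, 0, 4 and 8 ended these calls. The differences of list means, in that order, went from -0.33 to as little as -0.23, from -0.19 to -0.13, from -0.09 to -0.07 and from -0.15 to -0.09. The medians shrank to as little as -0.12, -0.10, -0.03 and -0.02, and the glucocorticoid median grew to as much as -0.32. Like the glucocorticoid and immediate early means, the NF-kB mean followed the neutrophil mean with group means removed (r = 0.771, rho = 0.778, r = 0.746 without the 2 samples farthest from the median). The permutation p was 8e-05 and 0.00012, the same after adjustment over the 3 relations, with the pairing of samples again ignored. Array quality weights kept 5 of the 10 list calls. In limma 0 genes passed, 169 had an unadjusted p under 0.05 (reached by 64 of 100 splits), and the lowest adjusted p was 0.998. The genes of smallest p, which did not pass, were higher for LBH (0.65, SE 0.23), SRSF1, a splicing factor (0.30, SE 0.10), HIVEP2 (0.21, SE 0.06), DUSP8 (0.19, SE 0.05) and SLC5A6 (0.18, SE 0.06). They were lower for PECAM1, an adhesion molecule of leukocytes and endothelium (-0.74, SE 0.21), TMEM164 (-0.68, SE 0.20), RETN, resistin (-0.45, SE 0.14), GDPD3 (-0.21, SE 0.06) and PDE8B (-0.19, SE 0.06). Other probe sets above the filter gave 0.07, 0.22 and 0.08 for SRSF1 and -0.33 and -0.40 for PECAM1.

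The differences of rejection and of follow-up from the same controls correlated across genes at r = 0.81 with a covariance of 0.0209. Groups simulated without any effect against shared controls gave 0.65 and 0.0168. That noise was independent between genes, so the simulation cannot show how widely r varies by chance. The gap between 0.81 and 0.65 therefore decides nothing. With no library shared between the comparisons, the median r was 0.19 (10th percentile -0.26, 90th percentile 0.45), and 69 of 100 draws lay above 0. Genes are not independent replicates in these correlations.

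A move of rejection genes toward the controls after treatment was not shown beyond chance. Of the 100 genes with the smallest p for rejection in one part of the patients, 60.7% changed in the opposite direction at follow-up in the other patients, against a median of 47.1% (range 22.97 to 74.57) when rejection and follow-up were swapped at random. The real value was reached in 15 of 100 draws (one-sided permutation p = 0.15). The change was small: averaged over the divisions, the median chosen difference was 0.51 and the median change along its sign was -0.03.

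The first 2 principal components held 37.6% and 25.2% of the variance and did not separate the groups (exact permutation p from 0.286 to 0.938). The fourth, with 4.37%, was 5.23 ± 3.63 in rejection, 0.31 ± 3.52 at follow-up and -5.54 ± 3.76 in controls. Its exact permutation p, two-sided, was 0.000583 for rejection against control, the smallest that 7 against 7 samples can give. Adjusted over the 18 tests of 6 components it was 0.0105. All 7 rejection samples lay above every control, but the lowest (-0.52) was close to the highest control (-0.54). The component score was lower at follow-up in 7 of 7 pairs (exact p = 0.0156, the smallest the pairs can give, 0.0938 adjusted). Follow-up differed from control with an exact p of 0.0122 (0.0938 adjusted).

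**Figure D3:**
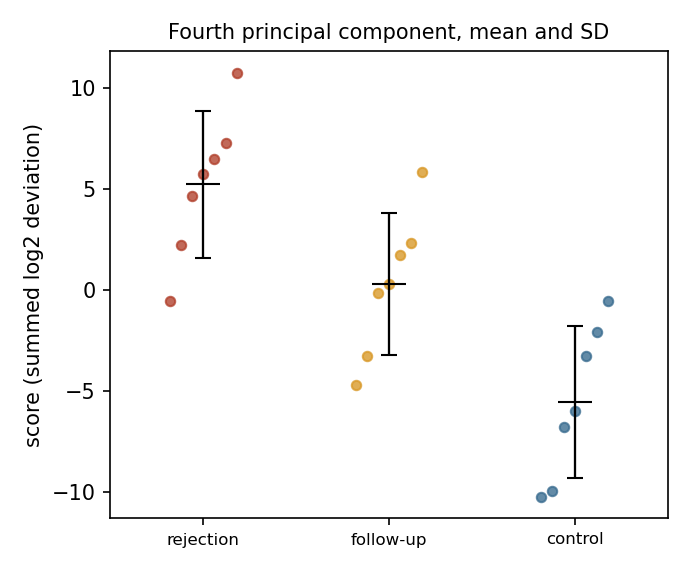
Score on the fourth principal component (vertical axis, summed log2 deviation) in the 7 samples of each group (horizontal axis), with points for samples and bars for the group mean and SD. All 7 rejection samples lie above every control, the lowest (-0.52) only just above the highest control (-0.54). The follow-up mean of 0.31 lies between the other group means.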

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

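List means and genes picked for naming, not all genes tested, were searched for a sample far from the other 6 of its group. The measure was the gap to the nearest sample over the range of the group. Of 348 such groups 17 exceeded Dixon's 95% critical value, and 17.4 are expected, since chance marks about 1 in 20. For 4 list means a single sample stood apart: the highest control for B cell markers (0.606), the lowest control for plasma cell genes (0.63), the highest rejection sample for eosinophil and basophil markers (0.614) and the highest follow-up sample for type I interferon genes (0.62). The interferon genes IFI27 (0.68) and OASL (0.583) also had a highest follow-up sample apart, and IFI27 a lowest control (0.597). The monocyte gene LYZ had a lowest sample apart in rejection (0.645), at follow-up (0.633) and in controls (0.62), and VCAN had one in controls (0.613). In rejection, CFLAR (0.711) and CXCL9 (0.573) had a lowest sample apart and SEMA7A a highest (0.655). At follow-up, DMTN had a lowest sample (0.575) and NDUFA1 a highest (0.705), and MKI67 had a lowest sample in controls (0.603). No explanation of these was tested.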

How the results depend on the processing

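The fits with covariates and those leaving out samples were chosen after seeing the data, and the other settings were chosen in advance. The count of 0 genes past the threshold held in all 3 comparisons under every setting chosen in advance, with 115 to 999 genes at an unadjusted p under 0.05. Rejection against control came nearest with array quality weights, at a lowest adjusted p of 0.070 in limma. With T cell and neutrophil list means as covariates, rejection against control gave 10 genes, and with the erythroid mean added 6. The same covariates gave 0 in the other comparisons, and the 3' minus 5' covariates gave 0 in all 3. Lists past the threshold numbered 9, 6 and 10 at the preset correlation and 0 in each comparison with an estimated correlation and with fry. Quantile normalization, no filter and the mean of all probe sets gave 8 lists for rejection against control, 5 to 9 for follow-up against rejection and 8 to 10 for follow-up against control. Array quality weights gave 6 lists for follow-up against control; of the calls in the 3 comparisons they kept 7 of 9, 4 of 6 and 5 of 10. Leaving out 1 sample at a time, or 1 pair, gave 4 to 12, 5 to 10 and 8 to 12 lists, and 0 genes (0 to 0) in each comparison. Without the patient pairing as a block, follow-up against rejection gave 3 lists and 0 genes. In the comparisons with controls, where the number pairs no patients, the block gave 10 and 9 lists and 0 genes. Of the list calls tried under the alternatives, 103 kept their direction and call and 72 kept their direction and lost the call. All 1169 values of named genes under the alternatives kept their direction and their side of the threshold. The side was fixed in advance, since 0 genes passed under each of these settings. Robust and untrended eBayes, the replicate block or its removal, and the fit of all 21 samples leave the difference itself unchanged. Testing probe sets singly keeps the probe set already used for a named gene. Of 50 other probe sets of these genes above the filter, 1, of USP34 at follow-up, turned direction, and below the filter TSR1 has others at -0.01 and -0.07. The return share was 58.1% to 65.2% with other gene numbers, quantile normalization and no filter (permutation p from 0.12 to 0.22), and 99% (null median 86%, p = 0.07) where the same rejection samples chose and measured the genes. The number of arrays limits what can be detected: the median half-width of a gene's 95% interval was 0.23, 0.20 and 0.21 on the log2 scale.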

Other observations

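The tests of random regroupings of the lists and of the adjusted fit, and the one on other probe sets, were set before their results were seen, and the other tests here were chosen after. The genes leading the fourth principal component were named after their values were seen. Toward rejection they included UQCRB, TUBB2A, the red cell genes FECH, BPGM and CA1, the platelet gene PPBP and the interferon genes IFI27 and IFIT1. Toward controls they included S100P, SCD5, PECAM1 and the granule genes CEACAM8, LCN2 and LTF. Of the 200 genes of largest weight, 10 erythroid, 5 platelet, 4 cytosolic ribosomal, 3 type I interferon and 2 blood rejection test panel genes pointed toward rejection, and 3 immature granulocyte genes toward controls. Of 4 cytotoxic genes weighted toward controls, 0 were lower in rejection, so weight and difference part there. TUBB2A, of the largest weight, differed between rejection and control by only 0.06, and the platelet gene ITGA2B by 0.003. A weight toward rejection is therefore not a higher signal in rejection.

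Other groupings of the same samples show how much of each result chance can give. For rejection against control, 53 of 100 splits gave at least 9 lists, and the highest other gave 18. For follow-up against rejection, 59 of the 64 swaps within patients gave at least 6 lists, the highest other giving 15, and for follow-up against control, 40 of 100 splits gave at least 10, the highest other giving 17. Chance is therefore not excluded for any of these list counts. For single genes the real counts were 0, which every grouping reaches (100 of 100, 64 of 64 and 100 of 100), so those counts say nothing about chance. The highest others called 56, 79 and 377 genes, which points to a structure among the samples whose source was not tested.

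With T cell and neutrophil list means as covariates, 10 genes passed between rejection and control, all lower in rejection, by a median of 0.61 (SE 0.09): HAUS2, ZNF160, ZNF721, ATP8B1, DBT, TSR1, FBXW12, USP34, PRR11 and POLR1B, named after their values were seen. With these covariates 1 split of 100, the real one, reached 10, the highest other giving 7. That repeats a fit picked among 9. With the highest count of the 3 covariate sets taken for each split, 4 of 100 reached 10 and the highest other gave 475, and the choice among the 3 comparisons was not covered, so the choice of fit leaves chance partly open. All 10 are measured by probe sets of the kind Affymetrix marks as able to bind other transcripts, against 9.74% of the genes tested. Their mean followed the Alu repeat control probe with group means removed (Pearson r = 0.931, Spearman rho = 0.938, permutation p = 1e-05 each, the smallest the permutations can give, also after adjustment over 2 relations, and r = 0.929 without the 2 samples farthest from the median), which is consistent with signal from Alu repeats, and that probe was itself lower in rejection (13.33 ± 0.18 against 13.51 ± 0.07, exact p = 0.0175, 0.262 adjusted over 15 tests) and stood at 13.48 ± 0.09 at follow-up (exact p = 0.125 against rejection). The permutations behind the relation with the Alu probe took the samples as independent, though rejection and follow-up samples share patients. With the Alu probe as a further covariate the median was 0.369 (SE 0.18) and 0 of the 10 still passed, as the difference shrank and its error grew. That leaves open whether less repeat-containing RNA in the rejection samples accounts for all of it.

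For the same 10 genes, RNA fragmentation is argued against, since the median stayed at 0.613 (SE 0.09) with the GAPDH and ACTB 3' minus 5' values added, and 8 of the 10 still passed. A test on other probe sets of these genes cannot decide, because 1 probe set, of USP34, lay above the filter. It differed by 0.0396 toward lower in rejection, against a bound of 0.31. The 10 genes may therefore report repeat-containing RNA in blood and not their own transcripts. Rejection as the source of a change in such RNA stays open and untested.

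The order of rejection, follow-up and control on the fourth component was set against technical measures. The difference between rejection and control was 10.8. It was 10.4 after the Alu probe and both 3' minus 5' values were regressed out within groups. The exact permutation p was again 0.000583, the smallest the test can give, so it cannot show a loss short of overlap. After the Alu probe alone the difference was 8.27 (exact p = 0.00175). Of the 10 genes above, 9 are among the 200 of largest weight, all toward controls. Among the 5503 genes whose r with the Alu probe stayed within 0.5, the component closest to the fourth (r = 0.902) also separated the groups (exact p = 0.000583). It was picked for that closeness, so its separation was largely given and adds no evidence of its own. The differences left after regressing out the technical measures argue against RNA fragmentation and repeat content, as far as these measures read them, as the whole of it. They leave open that repeat content gives a part. After the means of the T cell, cytotoxic, neutrophil, erythroid and platelet lists were regressed out the difference was 11.7, but the first 2 components, which the fourth cannot follow, already hold most of those means (median R² 0.781). That test decides nothing, and the share of cell types stays open, as do rejection and its treatment, the time between samples and the drugs given, which are not analysed here. The component was picked from 6.

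The fall of 2 lists at follow-up rests largely on few patients. Without the pair of the largest change, the median of the immature granulocyte list went from -0.338 to -0.114 and that of the erythroid list from -0.287 to -0.104. At the preset correlation both stayed past the threshold (adjusted p = 0.0182 and 0.0108), though 1 of the 7 omissions of a pair ended the erythroid call, and with an estimated correlation they did not (0.971 and 0.985). For the immature granulocyte list the largest change of a pair was -1.59 and the next -0.39, so 1 patient is a candidate source of most of its median. For the erythroid list they were -1.16 and -1.13, and without the second pair the median was -0.09, so no single patient stands apart and the tests leave its source open. The condition on the next pair was added after these values were seen. No other biological explanation was tested.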
